A study of Mus musculus with 8 samples.

How the data were processed

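Reduced representation bisulfite sequencing libraries were made from proximal colon organoids of male mice about 40 days old, taken from the proximal 2.5 cm of the colon, per the labels. Reads were 50 bp, single-end, with about 10% phiX added, per the labels' protocols. FastQC 0.11.7, Trim Galore 0.4.4, Bismark 0.14.3 and methylKit 1.7.4 and the mouse build GRCm38, also called mm10, are named in the submitters' processing notes; trimming settings, the coverage minimum and the conversion rate are not given in the sources used here. The 8 tables hold, for each of 4 within-line comparisons, the tiles that gained and the tiles that lost methylation. Per the file headers, each row gives a 200 bp tile, a p-value, a q-value and a methylation difference in percent, in the layout of methylKit, which the authors deposited. The values show that every listed tile differs by at least 20 points and has a q-value of at most 0.01; no tile outside these limits and no read count was used here. The depth is therefore unknown and no interval could be given for a tile.

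Replicates are the organoid lines 1 and 3. Each table compares 1 library with 1 library, so the authors' q-values describe those libraries and not the conditions. A lower bound of the number of tiles tested came from the ranks that the q-values imply, at 169516 and 176913 tiles for lines 1 and 3 with BrafV600E and 119237 and 213094 with age; the recovery was tested on simulated data, where it came within 0.1% of the true constant in 19 of 20 simulated tables of 150000 tiles. Where labels conflicted the title was used. This concerns the library titled 14 months, tagged 2 months, and the line 1 BrafV600E library, whose source name gives line 3.

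Tiles within 500 bp of each other were merged into regions whose direction is the sign of the summed difference, within a table for shares of gains and across all tables for comparisons between tables. Shares have exact Clopper-Pearson 95% intervals. Direction agreement between tables was tested with Fisher's exact test, two-sided, over regions listed in both. Genes came from a RefSeq gene table of GRCm38.p6 with 21895 genes in the universe (21887 protein coding and 8 list genes of other kinds). That table gives no strand, so a promoter could not be set; the window within 1 kb of either annotated end of a gene was used instead, which is a departure from the plan. Genes were hypermethylated in a line if at least 1 tile in that window gained and none lost, hypomethylated in the reverse case, and otherwise mixed. Genes with a tile in any table, 5896 in all, formed the background. Overlaps were set against the product of the counts over the background with Fisher's exact test. The background holds only genes listed somewhere, which raises the expected counts and lowers the odds ratios. An overlap at or below expectation therefore does not show a lack of sharing.

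The 16 gene lists were fixed before the data were examined: Wnt antagonists, intestinal identity regulators, intestinal stem cell genes, differentiated colon cell genes, the CpG island methylator phenotype panel, colorectal cancer methylation markers, cell cycle inhibitors and senescence genes, MAPK genes, TGF-beta and BMP genes, DNA methylation and chromatin writers, imprinted genes, germline genes, genes of mesenchymal, immune, endothelial and neural cells, epithelial junction genes, developmental transcription factors and clustered protocadherins. They hold 760 distinct genes, 39 of them in more than 1 list; 1 symbol of 502 given by name had no match. For each list the hypermethylated and hypomethylated members, counted in at least 1 line with no opposite call in the other, were compared with all other genes by Fisher's exact test with Benjamini-Hochberg adjustment over the 16 lists of a comparison at 0.05. Neighbouring genes of a cluster are not independent, so p-values of lists such as the protocadherins are too small. Some protocadherins, such as Pcdhga10 and Pcdhgc3, end at nearly the same position, so a tile there counts for each of them.

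Named genes were chosen by a rule fixed before the data were examined: genes listed in the same direction in both lines with no opposite tile, ranked by the smaller tile count of the lines and then by the smaller absolute mean difference, the first 12 hypermethylated and 8 hypomethylated per comparison, and up to 4 members of each list. Cdkn2a, Sfrp4, Sox17 and Cdx2 were looked up whatever they showed. Means over tiles are of the authors' deposited differences.

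Alternatives were an absolute difference of at least 40 points, q under 0.001, autosomes only, single tiles and merging within 100 or 2000 bp. Others were windows of 2 kb, at least 3 tiles per gene, and leaving out either line. The whole gene with 1 kb on either side was added after seeing the data. So was a count of genes with identical tiles as 1 locus (5601 loci). A comparison with all other genes was also added then. It set hypermethylated genes against all other background genes, whether hypomethylated, called in both directions or without a listed tile in that comparison. Its result therefore also reflects how likely a gene is to be listed. An in-silico digest background and matching on promoter CpG number need a genome sequence, and a logistic model needs counts, so these were not run. The agreement test gave 15.0 for a true odds ratio of 16 and 1.03 for a true value of 1 in simulations on the line 1 BrafV600E regions (11812). A planted list of 60 genes with calls, 90% of them hypermethylated, had an unadjusted Fisher's exact p under 0.05 in 100% of 200 simulations. An unchanged list had it in 3.5%. All lists but the developmental one held far fewer genes with calls and were judged after adjustment. The simulation therefore does not give the power for those lists. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.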

Results

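DNA methylation was profiled by reduced representation bisulfite sequencing, which reads CpG-rich fragments cut by a restriction enzyme, in organoids grown from the proximal colon of mice carrying a Cre-activable BrafV600E allele. BrafV600E is the constitutively active form of the BRAF kinase. The 8 libraries fall into 4 groups of 2, with organoid line 1 and organoid line 3 in each group. In the first group BrafV600E had been switched on with lentiviral Cre and the organoids were selected in Base medium, which lacks the stem-cell niche factors, at 5 months of culture. The second group received the empty lentiviral vector and was kept in full medium for 5 months. The remaining groups, both in full medium, are empty-vector organoids after 2 months, and empty-vector organoids kept for 12 months (line 1) or 14 months (line 3). All 8 libraries are labelled with a final culture of 3 weeks. The values analysed are the authors' own within-line comparisons of 200 bp tiles, each of 1 library against 1 library, restricted to tiles whose methylation differed by at least 20 percentage points at a q-value of at most 0.01. These tables hold no read counts, so the depth behind each tile is unknown, and no tile or gene has a replicate check within its line; the lines serve as the only replicates. A tile that is missing from a table may be unchanged or uncovered. A tile that was unmethylated in the control can be listed only as a gain and a fully methylated tile only as a loss, so regions can share a direction through their starting level alone, and methylation levels were not used here.

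BrafV600E organoids in Base medium were compared with empty-vector organoids of the same line at 5 months, which asks how methylation differs once the oncogene is active and growth no longer needs niche factors. At gene ends, Cdo1, Foxl2, Hoxd9, Msx2 and Cdx1 were among the genes hypermethylated in both lines, and Zeb1 and Ranbp17 among those hypomethylated in both. Cdo1, which encodes cysteine dioxygenase, gained most among the leading genes, by a mean of 91.9 points over 5 tiles in line 1 and 85.5 points over 7 tiles in line 3 of the authors' deposited tables. Cdx1, a homeobox regulator of intestinal identity, gained 62.8 points over 4 tiles in line 1 and 54.5 points over 5 tiles in line 3 in the authors' deposited tables, at tiles that the neighbouring gene Gm52351 shares, so the gain cannot be assigned to either. Zeb1, whose product represses epithelial genes, lost methylation, with mean differences of -45.4 and -75.3 points in lines 1 and 3 in the authors' deposited tables. The comparison joins the oncogene with the change of medium, and these cannot be separated in these libraries. The line 1 BrafV600E library has line 3 in another label field, and its title was followed.

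The authors' deposited tables list 15305 tiles for line 1, of which 10332 were hypermethylated and 4973 hypomethylated, and 29949 tiles for line 3, of which 12089 were hypermethylated and 17860 hypomethylated. The median listed gain was 42.8 points in line 1 and 44.1 points in line 3, and the median listed loss was -44.1 and -46.4 points in the authors' deposited tables. After tiles within 500 bp were merged, 62.6% of 11812 regions in line 1 were hypermethylated (exact 95% interval 61.7 to 63.5) against 35.9% of 24744 regions in line 3 (35.3 to 36.5). The balance of gains and losses therefore lay on opposite sides of an even split in the 2 lines, and the pooled share of 44.5% describes neither of them. Hypermethylated regions held 1.40 tiles on average in line 1 and 1.37 in line 3, and hypomethylated regions 1.12 in each.

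**Figure D1:**
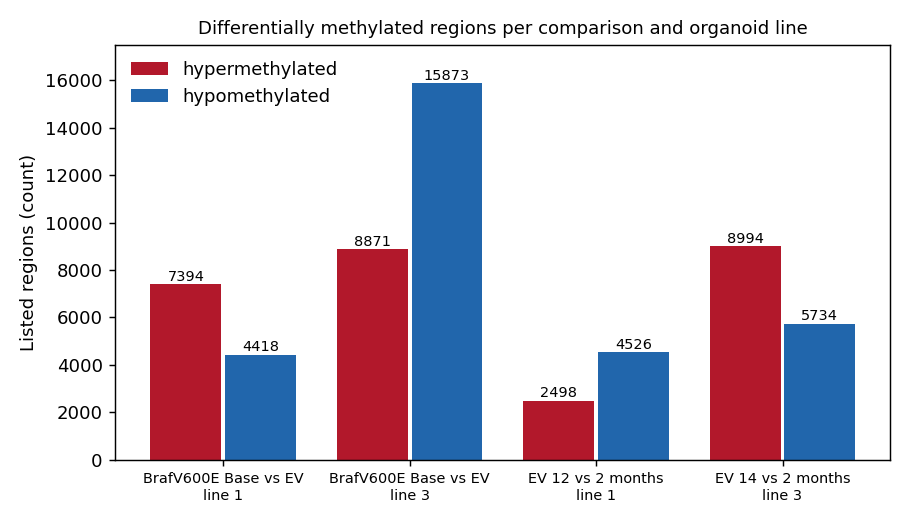
Hypermethylated and hypomethylated regions (listed tiles merged within 500 bp) per organoid line for each comparison, as numbers of regions. Gains outnumber losses in line 1 of the BrafV600E comparison and in line 3 of the ageing comparison, and losses outnumber gains in the others.

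Although the balance differed, regions listed in both lines mostly moved the same way. Of 5828 such regions 69.2% had the same direction, an odds ratio of 6.00 (95% interval 5.30 to 6.81) by Fisher's exact test. At single tiles, 5934 were listed in both lines where at most 2591 would be shared if listing were independent, and 73.9% of them had the same direction. Gains lay near annotated gene ends more often than losses did. In line 1, 28.5% of hypermethylated regions were within 1 kb of a gene end against 16.3% of hypomethylated regions (odds ratio 2.05, 1.86 to 2.25), and in line 3 the shares were 23.9% and 10.1% (odds ratio 2.80, 2.61 to 3.01). A region counted if any part of it reached the window, and hypermethylated regions held more tiles. Neither region width nor starting methylation was adjusted for in these odds ratios.

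At gene ends, 745 genes were hypermethylated in both lines, against 621 expected from 1965 genes in line 1 and 1864 in line 3 among the 5896 genes with a listed tile in any table (odds ratio 1.53, 1.37 to 1.72, Fisher's exact p = 3.11e-13). Hypomethylation was shared by 154 genes, against 160 expected (odds ratio 0.945, 0.776 to 1.15, Fisher's exact p = 0.598), and became an excess in 2 kb windows (235 against 211, Fisher's exact p = 0.0432) and with at least 3 tiles per gene (8 against 2.75, p = 0.0045). A further 322 genes were hypermethylated in line 1 and hypomethylated in line 3, and 125 the other way round. This background leaves out genes without a listed tile, which raises the expected counts. The 154 against 160 therefore do not show that losses were not shared between lines. Of 5934 tiles listed in both lines, 1389 were hypomethylated in both and 2994 hypermethylated in both. Another 1122 gained in line 1 and lost in line 3, and 429 did the reverse. The lines did not always change at the same tiles, since 571 of the 745 hypermethylated and 116 of the 154 hypomethylated genes had a tile listed in both lines.

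The leading hypermethylated genes included several encoding developmental transcription factors. In the authors' deposited tables Foxl2, a forkhead factor of the ovary (chromosome 9, 98955607 to 98958126), carried 9 hypermethylated tiles in line 1 with a mean of 41.0 points and 8 in line 3 with a mean of 48.9 points. Hoxd9 (chromosome 2, 74697763 to 74700208) had means of 56 and 45.6 points, Tfap2a 43.5 and 43.4, Nkx6-1 39.2 and 37.3, and Msx2 53.7 and 69.8 in the authors' deposited tables. Grip1, a scaffold for glutamate receptors, gained 73.0 and 69.3 points, and Tmem30b, a flippase subunit, 72.0 and 75.6, per the authors' deposited tables. For Galnt17, a glycosyltransferase, the means were 69.2 and 44.8 points in the authors' deposited tables, for Auts2 61.9 and 35.3, for the proteoglycan gene Spock1 49.8 and 50.2, and for the chondroitin synthase gene Chsy3 36.6 and 53.6.

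Of the 245 genes in the developmental homeobox and related transcription factor list, 90 were hypermethylated and 25 hypomethylated in at least 1 line with no opposite call, while 75 had calls in both directions. Their hypermethylated share of 78.3% (95% interval 69.6 to 85.4) exceeded the 62.5% of all other listed genes (Fisher's exact test, Benjamini-Hochberg adjusted p = 0.0063 over 16 lists). In both lines 44 members were hypermethylated and 4 hypomethylated, a split whose difference from other genes missed the threshold (Fisher's exact p = 0.115). With line 3 alone the share was 66.7% against 57.6% of other genes, and the call was lost (Fisher's exact test, adjusted p = 0.408). With at least 3 tiles per gene, or with hypermethylated genes set against all other genes, the call was lost as well. With at least 3 tiles the share stayed above that of other genes, at 92.9% against 83.0%, with only 52 hypermethylated and 4 hypomethylated members left (Fisher's exact p = 0.057, adjusted p = 0.912). Pitx1, Pax1, Neurog2 and Onecut3 were the members hypomethylated in both lines, with Pitx1 at -38.1 and -60.8 points in the authors' deposited tables. Pitx1, Pax1 and Onecut3 had 0 tiles listed in both lines, and the Pitx1 tiles of lines 1 and 3 lay at opposite ends of the gene.

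Among the 34 regulators of intestinal identity and differentiation, 11 were hypermethylated, 6 had calls in both directions and 0 were hypomethylated without an opposite call, which missed the threshold after adjustment (Fisher's exact p = 0.00928, adjusted p = 0.0742). Of the 34 genes, 14 are also in other lists. The hypermethylated Cdx1, Foxa1, Foxa2, Isl1, Neurod1, Nkx2-2 and Pax6 are also in the developmental list, so the results of these lists are not independent. Pdx1 was hypomethylated in line 1 and had tiles of both directions in line 3, and Neurog3 was hypermethylated in line 1 and hypomethylated in line 3. Besides Cdx1, Atoh1, the switch to secretory fate, gained 45.8 and 43.9 points and Creb3l1 41.5 and 39.9 points in lines 1 and 3 of the authors' deposited tables. Intestinal stem cell genes had 6 hypermethylated and 0 hypomethylated members, with 2 called in both directions (adjusted p = 0.291), among them Prom1 with gains of 89.7 and 67.4 points at 1 tile per line in the authors' deposited tables. Genes of differentiated colon cells had 3 and 2 (adjusted p = 1), with Chgb at 35.6 and 33.0 points in the authors' deposited tables. Chgb rested on 1 tile in each line, and Creb3l1 on 1 tile in line 1.

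Wnt antagonists and negative regulators had 15 hypermethylated and 4 hypomethylated members, with 7 called in both directions (Fisher's exact test, adjusted p = 0.48). Among those 7, Sfrp1, Nkd1 and Notum had opposite calls in the lines. Sox7 gained 37.7 and 40.1 points, Shisa3 30.9 and 34.9, Sfrp2 50.9 and 25, and Sox17 33.7 and 30.2 at its gene ends in the authors' deposited tables. Over the whole of Sox17 with 1 kb on either side (chromosome 1, gene 4490928 to 4497426), line 1 had 7 hypermethylated tiles with a mean of 49.2 points and line 3 had 9 with a mean of 45.6 points in the authors' deposited tables, and 0 tiles lost methylation. Over Cdkn2a, which encodes cell cycle inhibitors (chromosome 4, 89274473 to 89294619), line 1 had 2 hypomethylated tiles with a mean of -61.1 points and line 3 had 2 hypermethylated and 2 hypomethylated tiles in the authors' deposited tables. Sfrp4 carried 1 tile, at -65.4 points in line 3 of the authors' deposited tables, and Cdx2 carried 0.

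The remaining lists did not pass the threshold in Fisher's exact test. MAPK pathway and feedback genes had 9 hypermethylated and 4 hypomethylated members (adjusted p = 0.958), with the immediate-early gene Fos at 81.1 and 87.5 points, Erbb4 at 50.4 and 28.9, and the feedback inhibitor gene Spry4 at -59.1 and -25.6 in the authors' deposited tables. Colorectal cancer methylation markers had 13 and 3 (adjusted p = 0.48; Eya4 gained 52.0 and 52.2 points in the authors' deposited tables), and genes of the CpG island methylator phenotype panel 5 and 3 (adjusted p = 1; Rassf2 gained 44.1 and 30.0 points). TGF-beta and BMP genes had 11 and 4 (adjusted p = 0.791), with Gdf7 at 42.3 and 45.4 points in the authors' deposited tables. DNA methylation and chromatin writers had 6 and 1 (adjusted p = 0.48), among them Uhrf2 at 64.2 and 45.2 points, the 5-methylcytosine oxidase gene Tet1 at 39.3 and 25.6, and the Polycomb gene Cbx8 at 46.4 and 39.6 in the authors' deposited tables. Epithelial junction genes had 7 and 1 (adjusted p = 0.48; Tjp1 gained 35.3 and 26.3 points in the authors' deposited tables), and cell cycle inhibitors and senescence genes 3 and 0, with 2 called in both directions (adjusted p = 0.48; Igfbp7 gained 25.7 and 21.3 points). Imprinted genes had 11 and 7 (adjusted p = 1), with Dio3 at 48.6 and 44.2 points and Phlda2 at -64.7 and -34.5 in the authors' deposited tables. Rassf2, Igfbp7 and Phlda2 rested on 1 tile in each line. Fos and Spry4 had 1 tile in line 3, and Cbx8 had 1 tile in line 1. Clustered protocadherins had 9 and 12 (adjusted p = 0.278), germline genes 3 and 7 (adjusted p = 0.243), and genes of mesenchymal, immune, endothelial and neural cells 10 and 3 (adjusted p = 0.574, all by Fisher's exact test). The majority direction was opposite in the 2 lines for 3 lists: protocadherins, with 6 hypermethylated and 1 hypomethylated in line 1 and 8 and 13 in line 3, the methylator phenotype panel, with 5 and 0 and then 3 and 5, and germline genes, with 2 and 1 and then 2 and 7.

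The leading hypomethylated genes were Ranbp17, Zeb1, Ror2, Ndufa13, Tssk6, Zfp287, Pitx1 and Arap1. Ranbp17 had means of -59.4 and -87.1 points in lines 1 and 3, Zfp287 -79.2 and -39.0, the Wnt5a receptor gene Ror2 -69.7 and -39.7, and Arap1 -43.9 and -33.0 in the authors' deposited tables. Ndufa13 and Tssk6 share the same tiles, at -62.0 and -27.2 points in the authors' deposited tables, so the loss cannot be assigned to either gene.

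Empty-vector organoids kept for 12 or 14 months were compared with 2-month organoids of the same line, which asks how methylation differs after long culture without the oncogene. Developmental transcription factor genes were hypermethylated far more often than hypomethylated, 132 against 8, with 36 called in both directions. The synaptic gene Rims2 led with 9 hypermethylated tiles in each line, at means of 54.4 and 53.4 points in lines 1 and 3 of the authors' deposited tables. The homeobox gene Nkx1-1 gained 38.8 and 49.3 points and Bnc1, which encodes basonuclin, 59.6 and 58.6 points in the authors' deposited tables. Hoxd9, hypermethylated in the BrafV600E comparison, lost methylation here, at -29.0 and -38.2 points in the authors' deposited tables, at different tiles in each line. That loss rested on 1 tile in line 1 and 4 in line 3. The line 3 library titled as 14 months carries a culture time of 2 months in another label field, and the title and description were followed.

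The authors' deposited tables list 8263 tiles for line 1, with 3380 hypermethylated and 4883 hypomethylated, and 21524 for line 3, with 15485 hypermethylated and 6039 hypomethylated. The median gain was 39.5 and 44.2 points and the median loss -47.2 and -46.2 points in lines 1 and 3 of the authors' deposited tables. Of 7024 regions in line 1, 35.6% were hypermethylated (exact 95% interval 34.4 to 36.7), and of 14728 in line 3, 61.1% (60.3 to 61.9), the reverse of the order seen with BrafV600E. The pooled share was 52.8%. Hypermethylated regions held 1.36 tiles in line 1 and 1.72 in line 3, hypomethylated regions 1.07 and 1.05. Gains again lay near gene ends more often than losses, at 42.5% against 19.6% in line 1 (odds ratio 3.03, 2.71 to 3.38) and 31.4% against 11.7% in line 3 (odds ratio 3.44, 3.14 to 3.78). Region width and starting methylation were again not adjusted for.

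The 3032 regions listed in both lines had the same direction in 63.7% of cases (odds ratio 6.27, 5.06 to 7.83, Fisher's exact test). At gene ends, 657 genes were hypermethylated in both lines against 449 expected (odds ratio 2.81, 2.43 to 3.26, Fisher's exact p = 8.72e-48), and 83 were hypomethylated in both against 90.2 expected (odds ratio 0.898, 0.695 to 1.15, p = 0.434). With at least 3 tiles per gene, 79 hypermethylated genes were shared against 74.1 expected (Fisher's exact p = 0.336). There 79 of 109 line 1 genes were shared, but 916 of the 1348 background genes were hypermethylated in line 3. The lost excess therefore does not show less sharing. At differences of at least 40 points, 23 hypomethylated genes were shared against 37.9 expected (Fisher's exact p = 0.00675). That background of 4115 listed genes raises the expected count, so no deficit is shown, and the same limit holds for the 83 genes. Of 3220 tiles listed in both lines, 451 were hypomethylated in both, 1754 hypermethylated in both, and 106 and 909 opposed. Among genes called in opposite directions, 381 were hypomethylated in line 1 and hypermethylated in line 3, and 37 the other way round. A tile listed in both lines was present in 547 of the 657 hypermethylated and 40 of the 83 hypomethylated genes.

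Developmental transcription factor genes had a hypermethylated share of 94.3% (89.1 to 97.5) against 71.2% of other genes (Fisher's exact test, adjusted p = 2.67e-10 over 16 lists). The call held in each line alone by Fisher's exact test, with adjusted p = 1.38e-05 in line 1 and 7.12e-07 in line 3, and was lost with at least 3 tiles per gene, where 98.0% of members and 97.2% of other genes were hypermethylated. In both lines, 65 members were hypermethylated and 2, Hoxd9 and Hoxb13, hypomethylated, both at different tiles in each line (Fisher's exact p = 0.0237, adjusted p = 0.38). In the authors' deposited tables Barhl2 gained 37.2 and 56.6 points in lines 1 and 3, Irx3 39.4 and 51.0, and Hoxc13 60.8 and 50.4. Other leading genes were Prdm16 at 44.7 and 67.8 points, Bend4 at 35.2 and 61.2, 1110032F04Rik at 51.8 and 75.5, the cadherin gene Cdh4 at 37.6 and 42.1, Eif4e3 at 38.1 and 53.2, the adrenergic receptor gene Adra1d at 43.3 and 41.4, and Ube2ql1 at 24.9 and 45.6 in the authors' deposited tables.

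Regulators of intestinal identity had 13 hypermethylated and 0 hypomethylated members, with 3 called in both directions (Fisher's exact p = 0.0255, adjusted p = 0.102). This list again overlaps the developmental one, which also holds Nkx2-2, Neurod1 and Pou2f3. The enteroendocrine factors Nkx2-2, at 60.9 and 32.0 points, and Neurod1, at 24.0 and 75.2, and the tuft cell factor Pou2f3, at 55.2 and 40.0, were among those hypermethylated in both lines of the authors' deposited tables. Differentiated colon cell genes had 6 and 0, with 1 called in both directions (adjusted p = 0.352), with Chga at 33.2 and 34.8 points in the authors' deposited tables, and intestinal stem cell genes 2 and 1 (adjusted p = 1). Neurod1 rested on 1 tile in each line, Nkx2-2 and Chga on 1 in line 1, and Pou2f3 on 1 in line 3.

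Colorectal cancer methylation markers had 21 hypermethylated and 2 hypomethylated members (Fisher's exact p = 0.0372, adjusted p = 0.119). Among them were Ikzf1 at 34.1 and 45.7 points, Pcdh10 at 44.6 and 41.9, Fbn1 at 28.9 and 58.2, and Vim at 33.9 and 41.1 in the authors' deposited tables. Of members with a tile in any table, 75% were hypermethylated here, against 41.7% of other such genes (Fisher's exact test, adjusted p = 0.00345). That share also reflects how likely a gene is to be listed. The CpG island methylator phenotype panel had 10 and 1 (adjusted p = 0.495), with Gata5 at 49.5 and 70.2 points and the cytokine signalling inhibitor gene Socs1 at 57.3 and 48.8 in the authors' deposited tables. Wnt antagonists had 14 and 6 (Fisher's exact test, adjusted p = 0.991). Among them Frzb gained 54.6 and 50.0 points, Apcdd1 63.7 and 43.0, and Sox7 39.8 and 48.4, while Dact2 stood at -23.1 and -29.4 in the authors' deposited tables; the Apcdd1 tiles differed between lines. Over the whole of Sox17, 8 hypermethylated tiles in line 1 averaged 47.8 points and 9 in line 3 averaged 54.1 points in the authors' deposited tables. Cdkn2a carried 0 listed tiles in line 1 and 4 hypermethylated tiles in line 3 with a mean of 36.3 points in the authors' deposited tables. Sfrp4 and Cdx2 carried 0 in either line. Of the list members above, Dact2 rested on 1 tile in each line. Frzb and Apcdd1 had 1 tile in line 1, and Vim had 1 in line 3.

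**Figure D2:**
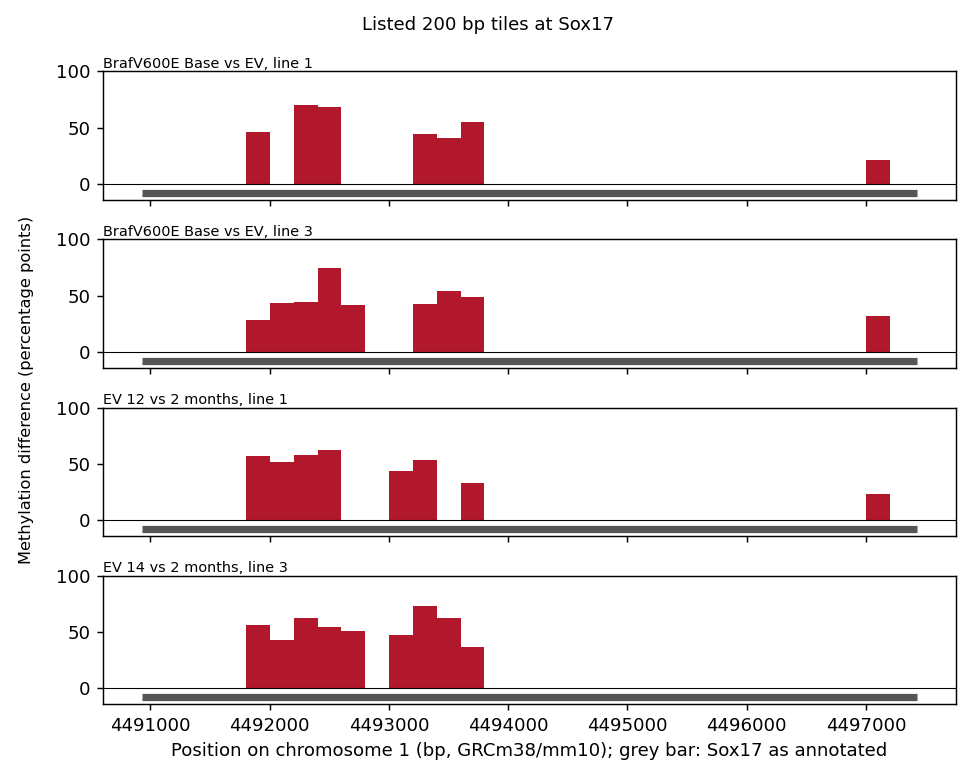
Methylation difference in percentage points of each listed 200 bp tile along Sox17 on chromosome 1, for both lines of both comparisons. The 7, 9, 8 and 9 listed tiles all lie above 0, between 21.6 and 74.4 points.

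Cell cycle inhibitors and senescence genes had 3 hypermethylated and 6 hypomethylated members (p = 0.0173, adjusted p = 0.102), and DNA methylation and chromatin writers 3 and 4 (adjusted p = 0.266), with Uhrf2 at 53.4 and 33.7 points and Phc2 at 25.5 and 43.8 in the authors' deposited tables. Clustered protocadherins had 23 and 2 (Fisher's exact p = 0.0244, adjusted p = 0.102), among them Pcdhgc3 at 32.3 and 69.0 points in the authors' deposited tables. Hypermethylated members set against all other genes gave an adjusted Fisher's exact p of 0.0111. A line 3 tile ending at 37842600 lay past the gene end that Pcdhgc3 (37841873) nearly shares with Pcdhga10 (37841870). Such a tile counts for each gene ending there, so these counts and p-values do not describe independent genes. Genes of mesenchymal, immune, endothelial and neural cells had 11 and 1 (adjusted p = 0.352), with Zeb1 at 45.2 and 57.5 points, Zeb2 at 55.8 and 44.8 (at different tiles in each line) and Des at 49.3 and 49.9 in the authors' deposited tables. TGF-beta and BMP genes had 13 and 3 (adjusted p = 0.843), with Inhbb at 36.4 and 61.0 points and Bmp6 at 60.1 and 45.9 in the authors' deposited tables. Pcdhgc3, Zeb1, Zeb2, Des and Bmp6 had 1 tile each in line 1. Imprinted genes had 13 and 4 (adjusted p = 0.991; Grb10 gained 32.1 and 51.8 points in the authors' deposited tables), MAPK genes 6 and 2 (adjusted p = 1; Rasgrf1 gained 64.3 and 65.5 points), germline genes 4 and 5 (adjusted p = 0.291; Slc25a31 stood at -53.7 and -27.0 points, at different tiles in each line), and epithelial junction genes 2 and 1 (adjusted p = 1). Slc25a31 rested on 1 tile in each line. The majority direction was opposite in the 2 lines for 6 lists. Protocadherins had 2 hypermethylated and 5 hypomethylated members in line 1 and 25 and 0 in line 3, imprinted genes 3 and 8 and then 17 and 0, and germline genes 1 and 4 and then 3 and 2. The protocadherin counts can hold the same tile more than once, as described above. Chromatin writers had 2 and 3 and then 4 and 2, and stem cell genes and junction genes each 0 and 1 and then 3 and 1.

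The leading hypomethylated genes rested on 1 or 2 tiles per line. Cmklr1, a chemoattractant receptor gene, stood at -88.2 and -100 points in lines 1 and 3, the calcium sensor gene Stim2 at -90.9 and -66.7, Sh3tc2 at -95.8 and -28.7, and Tmem117 at -24.9 and -21.1 in the authors' deposited tables. Tmprss12 stood at -64.1 and -74.7 points, Gpr137 at -66.9 and -56.3, Tlr12 at -54.8 and -53.0, and the pseudokinase gene Trib3 at -65.0 and -51.6 in the authors' deposited tables. The tiles of Cmklr1 and of Tlr12 differed between lines.

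**Figure D3:**
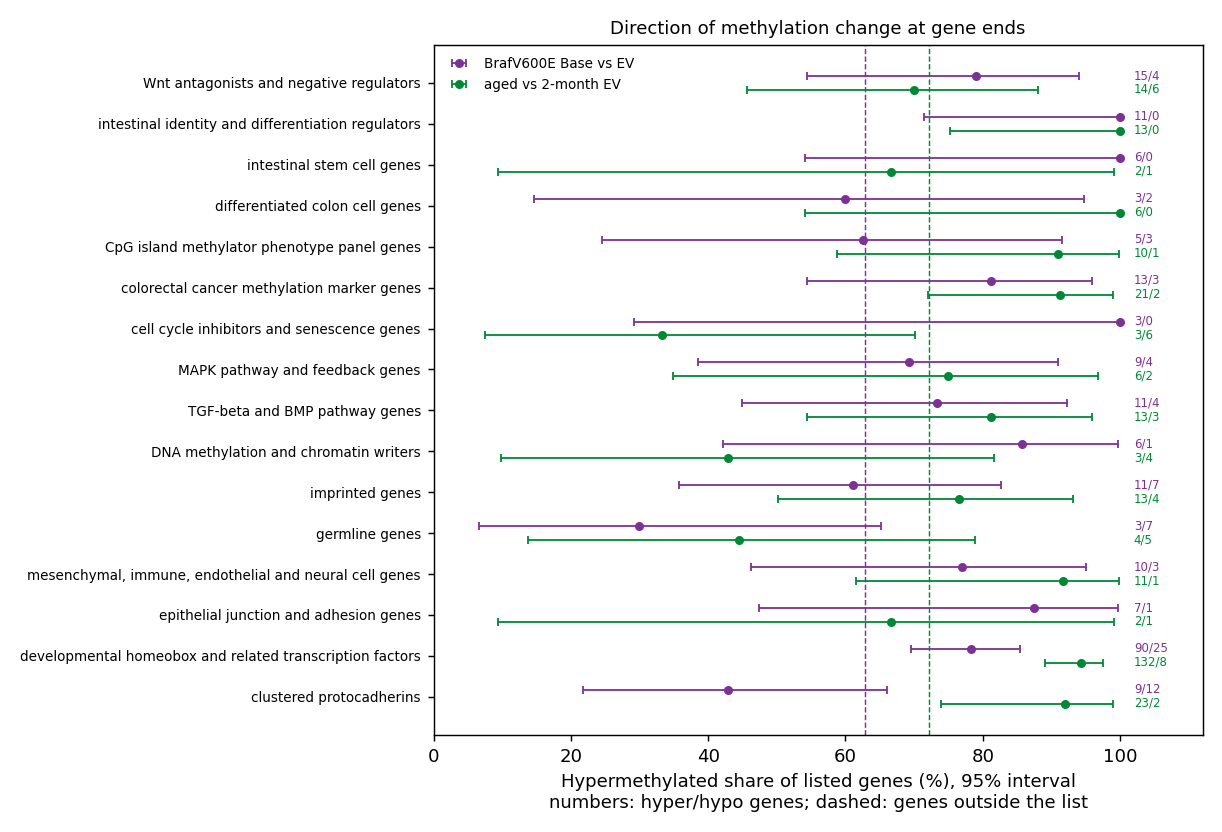
Percent of listed genes that were hypermethylated at a gene end, for each of the 16 gene lists, with exact 95% intervals and the numbers of hypermethylated and hypomethylated genes; dashed lines give the median over lists of the share among genes outside a list. Developmental transcription factors lie at 78.3% with BrafV600E and 94.3% with age.

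The comparisons were then set against each other, which asks whether BrafV600E organoids in Base medium and long-cultured organoids changed at the same genes and regions. Genes were matched by the windows at their ends, so a shared gene need not share tiles. Bnc1, Nkx1-1, Msx2, Sox7 and Uhrf2 were among 147 genes hypermethylated at gene ends in both lines of both comparisons, against 83.0 expected (odds ratio 2.24, 1.81 to 2.75, Fisher's exact p = 1.45e-13). Spp2, Spib and Krtdap, named because the count is small and after their values were seen, were the 3 genes hypomethylated throughout, against 2.17 expected. Another 27 genes were hypomethylated with BrafV600E and hypermethylated with age, against 17.2 expected (odds ratio 1.72, 1.09 to 2.65, Fisher's exact p = 0.0185), among them Zeb1, Ranbp17, Zfp287, Pax1 and Onecut3. Some of these genes share all their tiles, such as Ndufa13 with Tssk6 and Bend6 with Dst; with such genes counted once, a count chosen after seeing the data, 25 remained against 17 expected, with an interval that includes 1 (odds ratio 1.59, 0.984 to 2.49, Fisher's exact p = 0.0483). The 9 with the opposite pattern, against 10.5 expected, included Cdo1, Hoxd9 and Trib3. Cdo1 stood at -50.3 and -36.7 points with age in the authors' deposited tables.

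Directions of shared regions matched across lines more than within a line. The odds ratio of equal direction was 3.98 (3.41 to 4.64) between BrafV600E in line 1 and age in line 3 over 4346 regions, and 4.24 (3.68 to 4.88) between BrafV600E in line 3 and age in line 1 over 3751 regions. Within line 1 it was 1.31 (1.10 to 1.57, Fisher's exact p = 0.00226, 2673 regions) and within line 3 it was 0.997 (0.896 to 1.11, p = 0.978, 6365 regions). The value within line 1 was 1.22, 1.15 and 0.997 with larger differences, smaller q-values and single tiles, none past the threshold of Fisher's exact test.

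**Figure D4:**
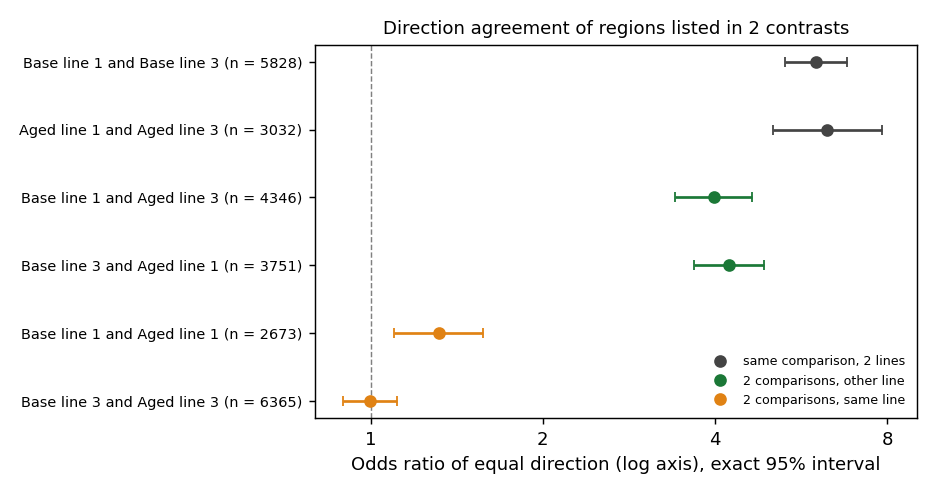
Odds ratio of equal direction (log axis) for regions listed in each of 6 pairs of comparisons, with exact 95% intervals and the number of regions; the dashed line marks 1. Pairs of different lines lie between 3.98 and 6.27, and the pairs of the same line at 1.31 and 0.997.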

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

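All tests in this part except that of weakly called tiles were chosen after the result was seen. The share of hypermethylated regions differed between the lines under the same contrast, by 26.7 points (25.7 to 27.8) for line 1 minus line 3 with BrafV600E in Base medium and by -25.5 points (-26.9 to -24.1) with age. Weakly called tiles as the whole cause are argued against, since the smaller gap between lines at q under 0.001 was still 26.3 points. Incomplete bisulfite conversion of a library stays open, because every listed tile already differs by at least 20 points, so that a lowest share of 49.1% of gains reaching 40 points does not bear on the balance of gains and losses. Unequal coverage and a lasting difference between the organoid lines also stay open, neither tested, since the tables give no depth. With 1 library per arm, a property of single libraries cannot be set apart from one of the line.

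The ageing direction equalled the BrafV600E direction of the same line in 55.4% of 1841 regions in line 1 and 56.5% of 2836 regions in line 3, against 62.7% and 75.1% for the other line (exact paired p = 2.24e-07 and 3.58e-64). A candidate explanation is drift of each empty-vector culture, already present in the 5-month control and continuing to the aged library, since such drift would enter the BrafV600E comparison with the opposite sign. The own-line minus other-line agreement of -7.39 points in the line with the smaller difference is the observation that prompted this explanation and does not test it, and part of the gap follows from the opposite shares of gains in the lines; the odds ratios of 1.31 and 0.997 within a line against 3.98 and 4.24 across lines do not depend on those shares. An exchange of lines between the ageing tables, or between the BrafV600E tables, where the line 1 library has line 3 in another label field, could give the same pattern, and the ratio of own-line to other-line overlap of regions, 1.04, does not decide it, so drift and exchange cannot be told apart.

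The library titled 14 months carries a culture time tag of 2 months. If it were a 2-month culture, its table would compare libraries of the same age, and the directions might match those of the 12-month table no more than by chance. The odds ratio of equal direction was 6.27, but this cannot be told apart from a matching that arises because unmethylated tiles can only gain and methylated tiles can only lose, which would also hold between libraries of the same age. No biological explanation was tested for this label.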

How the results depend on the processing

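Among main results recomputed under alternatives, 160 values kept their direction and their side of the threshold or stayed within 1.5 times the count. Another 22 counts moved further than that, 5 values reversed, 4 lost significance and 1 became significant. The cause of these exceptions was not tested unless given. Among values of single lists, 273 kept their direction and side of the threshold, 6 became significant and 4 lost significance. The odds ratio within line 1 between comparisons was 1.22 at 40 points and 1.15 at q under 0.001, no longer significant, and reversed to 0.997 over single tiles. Genes shared by both lines numbered 343 hypermethylated and 61 hypomethylated with BrafV600E and 292 and 23 with age at 40 points; 109, 8, 79 and 0 with at least 3 tiles per gene, where fewer genes can pass by construction. The overlap between lines changed its call for hypermethylated genes with age at 3 tiles (79 against 74.1 expected, odds ratio 1.26, no longer significant). For hypomethylated genes with age at 40 points it fell below the expected count (23 against 37.9, odds ratio 0.555). For hypomethylated genes with BrafV600E it reversed to an excess in 2 kb windows (235 against 211, odds ratio 1.18) and at 3 tiles (8 against 2.75, odds ratio 3.62). Each background holds only genes listed under its setting, which raises the expected counts. Neither the lost excess nor the low count with age therefore shows less sharing. Hypomethylated genes in both lines numbered 43 with age at q under 0.001, 235 with BrafV600E and 128 with age in 2 kb windows, and 345 and 234 over the whole gene, an alternative chosen after seeing the data, where wider windows take in more tiles. Lists past the threshold, 1 in each comparison, became 2 with BrafV600E at q under 0.001 (germline genes joined as mostly hypomethylated), 2 in 2 kb windows in each comparison (protocadherins joined in opposite directions, with 7 hypermethylated and 17 hypomethylated with BrafV600E and 24 and 2 with age, a contrast of line 3 that line 1 alone turned round in 1 kb windows), 0 in each with at least 3 tiles, 2 with BrafV600E over the whole gene (junction genes joined), and 0 with BrafV600E and 3 with age against all other genes (colorectal cancer markers and protocadherins joined), the last also chosen after seeing the data. Protocadherins with a common end share tiles there, so their joining does not rest on independent genes. The pooled hypermethylated share with BrafV600E was 49.5% over single tiles, no longer below an even split by test. Leaving out a line gave 35.9% to 62.6% with BrafV600E and 35.6% to 61.1% with age, reversed without line 3 in both, and 0 to 1 lists with BrafV600E. Of 113 named genes counted per comparison, those keeping their direction in both lines numbered 70 at 40 points, 96 at q under 0.001 and 113 on autosomes. In 2 kb windows 105 kept it, with at least 3 tiles 41, and over the whole gene 74. A reversal could not occur, since these genes had no opposite tile and each setting only removed tiles or added to them. No paired analysis was possible because the tables are already within-line comparisons and give no values per library. The in-silico digest background, matching on CpG number and the replicate block were not run. Unknown depth leaves open how many missing tiles were covered.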

Other observations

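Several genes outside the fixed lists moved in opposite directions in the comparisons. Of the 27 genes that lost methylation with BrafV600E and gained it with age in both lines, Notch3, a Notch receptor gene, stood at -29.8 and -30.3 points and then at 39.6 and 20.2 points in lines 1 and 3 of the authors' deposited tables. Unc93b1, which carries nucleic acid-sensing Toll-like receptors to endosomes, stood at -55.5 and -41.6 and then at 85.3 and 32.7 points in the authors' deposited tables. In the 9 genes with the opposite pattern, the matricellular gene Ccn1 stood at 43.7 and 69.5 and then at -45.7 and -85.5 points, and the collagen receptor gene Ddr1 at 38.1 and 71.1 and then at -80.2 and -20.7 in the authors' deposited tables. These 4 genes were chosen after their values were seen.

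Among the 147 genes hypermethylated in both lines of both comparisons, the developmental list supplied Hoxd12, Zic1, Zic4 and Tlx2, and Gbx2, Sall1 and Sim1 encode developmental transcription factors outside it, chosen after their values were seen. Zic1 and Zic4 are neighbours with the same smallest and largest mean differences, 29.1 and 44.6 points.

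Of 198 genes of the developmental list with a tile in any table, 16 (8.08%) were hypermethylated in all 4 line comparisons, against 131 of 5698 other genes (2.30%), an odds ratio of 3.73 (2.03 to 6.46, Fisher's exact p = 2.88e-05). This count was made because developmental regulators stood out among the 147 genes, so it describes them and is not an independent test. With BrafV600E, hypermethylated members set against all other listed genes gave 45.5% against 40.1% (Fisher's exact test, adjusted p = 0.455), and the call was also lost in line 3 alone. Tiles unmethylated at the start can only gain, and baseline levels were not used here.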
